A study of Homo sapiens with 13 samples.

How the data were processed

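Exosomes were isolated from the supernatant of cultured BM-MSCs of 13 donors, and their miRNAs were measured by RT-qPCR on TaqMan low density array cards after reverse transcription of 60 ng of RNA and preamplification, per the labels' protocols. Groups were taken from the sample titles, as normal (4), MM (7) and MGUS (2). The deposited tables were a table of Ct, a table of normalized values and a table of fold values, each with 746 assays.

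The authors' Ct table held values from 10.05 to 39.91. A value of 39, found in 5058 readings (52.2%), was read as undetermined. The authors' normalized table is on a log2 scale (delta delta Ct, per the file headers; a higher value means less miRNA). For each card and sample it equals the Ct minus 1 constant, and minus the value of normal 3, to within 5e-09. The series' design text names mean expression normalization; the constants themselves are not given in the sources used here. Only their shift relative to normal 3 can be computed; this shift differed between the cards by up to 0.08 cycles in the other normal samples, by 1.76 in MM 2 and by 1.44 in MGUS 1. The authors' fold table is a ratio, 2 to the power of minus delta delta Ct, and it equals the normalized table to within 3.83e-06 on the log2 scale. The cards were told apart by the length of the assay codes. No small-RNA control (U6, RNU44, RNU48) was used here, because none had a row.

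In the decimals of the Ct table the digit pair 40 occurred 5 times and 41 occurred 0 times, while 39 occurred 522 times and the other pairs from 36 to 45 occurred 179 to 274 times each. No assay name held 40 or 41, and 24 held 39. A replacement of 40 and 41 by 39 throughout the table would give this. It would move a Ct by at most 0.02 cycles in its first decimals and read a Ct of 40 as undetermined, but the miRNA meant by those 24 names is uncertain; they stayed in the fits under the printed name and were left out of all lists. Assays whose name occurs more than once are given with their assay code.

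A reading was called detected at a Ct of 35 or below. Readings not detected were set to 35, so differences from them depend on this limit. From each sample the mean Ct of its own detected assays was subtracted and the sign turned (minus delta Ct, a log2 scale). Assays detected in at least 4 of the 13 samples were tested, 364 in all, of which 233 were on card A and 131 on card B; 296 assays were detected in no sample. All 13 samples entered 1 fit with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 3 group means, no block, Benjamini-Hochberg adjustment and a threshold of 0.05. For MM against normal, an exact permutation test per assay over the 330 arrangements of the samples was added.

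The number of detected assays and the mean raw Ct were compared by exact two-sided permutation tests, whose smallest possible p is 0.00303 for 7 against 4. Detection per assay was compared by Fisher's exact test. Of 25 lists of miRNAs (families, a cluster, reported sets and markers of cell types) written before the data were examined, 22 had at least 3 tested members and were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. The miR-181 family, the endothelial list and the placental chromosome 19 cluster had 2 tested members each and were not tested as lists. Markers of cell types were white blood cells, red cells, endothelium, muscle, liver, epithelium, nervous tissue, placenta and mesenchymal stromal cells; none of the tested blood markers stood in the mesenchymal list.

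The miRNAs named were fixed by rule before the data were examined. They are, per comparison, the passing assays with the largest fold change, up to 10 in each direction (5 with MGUS), or where fewer than 5 pass, the 5 in each direction with the smallest p. Also named were up to 4 members of each list with the smallest p, a fixed set that includes miR-15a, and up to 5 assays in each direction with the smallest Fisher p. miR-222#, miR-425#, miR-15a#, miR-16-1#, miR-106a and other miRNAs given only for their spread, their strand or a call under another setting were chosen after their values were seen.

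The fit was tested on 20 simulated tables for MM against normal with 364 assays each, of which 60 were changed. It recovered 12.3% of changes of 1, 44% of changes of 2 and 82.3% of changes of 4 on the log2 scale, with 5.46% of calls false. A list shifted by 1.5 was called in 20 of 20 tables. Noise was drawn independently for each assay, apart from 1 shift per sample. In the data, the estimated correlation within the shifted list, the mesenchymal markers, was 0.39 for MM against normal. These rates therefore do not cover correlated assays. Alternatives planned before the data were examined were other detection limits (Ct 32 and 40), missing values, other filters, other normalizations, the authors' table, other fits, the replicate number as a block and leaving out each sample. Added afterwards were raw Ct, the common mean within each card, and leaving out MM 3, 4, 5 and 7 or MM 2 and MGUS 1. Whether abundant and rare assays rose alike was also examined on the 305 assays detected in all normal samples, by medians with readings not detected above every Ct and a bootstrap over assays (2000 draws). No 2 samples were copies of each other (highest correlation across assays 0.95).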

Results

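MicroRNAs (miRNAs) were measured in exosomes, small vesicles released by cells, that had been isolated from the culture supernatant of bone marrow mesenchymal stromal cells (BM-MSCs). The 13 preparations came from 4 healthy donors (normal), 7 donors with multiple myeloma (MM), a cancer of plasma cells in the bone marrow, and 2 donors with monoclonal gammopathy of undetermined significance (MGUS), a precursor condition. Each preparation was read in 746 single-well TaqMan assays on 2 array cards, A and B. A reading is the quantification cycle (Ct), which falls by 1 when the template doubles. The comparisons ask which miRNAs differ in abundance between exosomes of stromal cells from patients and from healthy donors. Each assay was read once per preparation, so the number of preparations limits the precision.

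The preparations carried miRNAs typical of mesenchymal cells together with miRNAs typical of blood cells. All 16 measured mesenchymal markers were detected in all 13 preparations, with a median Ct of 19.08 in the normal group. Among them were miR-222 at Ct 14.85 ± 0.93, miR-21 at 16.86 ± 0.63, miR-125b at 17.79 ± 0.74 and miR-145 at 17.79 ± 0.95 (mean ± SD, n = 4 normal). The white blood cell miRNA miR-223 read 15.63 ± 0.26 and the red cell miRNA miR-451 read 17.19 ± 0.21 in the same samples, within the range of the mesenchymal markers. Markers of white blood cells were detected in 87.5% of readings in each group. miR-155, an activation marker of lymphocytes, was not detected in any preparation. Of the endothelial and platelet list, both measured members were detected in every preparation. Of the 37 measured members of the placental chromosome 19 cluster, 8.78% of normal readings, 7.34% of MM readings and 8.11% of MGUS readings were detected.

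Blood markers and mesenchymal markers differed in how evenly they appeared across donors, a comparison chosen after the values were seen. The blood markers here are the members of the white blood cell, red cell, and endothelial and platelet lists that were detected in every preparation. In the 4 normal preparations, the median SD of raw Ct was 0.32 cycles over 14 blood markers and 0.86 cycles over 16 mesenchymal markers. The 12 members of the miR-17 clusters and their paralogs had a median SD of 0.12 cycles there, with 0.03 for miR-106a and 0.04 for miR-93. In the 7 MM preparations the medians were 1.48 for blood markers, 0.82 for mesenchymal markers and 0.81 for the miR-17 clusters. Over all 242 assays detected in all 13 preparations, the median SD was 0.60 in normal and 1.00 in MM. A larger spread in MM was thus not particular to the blood markers, and the mesenchymal markers did not share it.

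**Figure D1:**
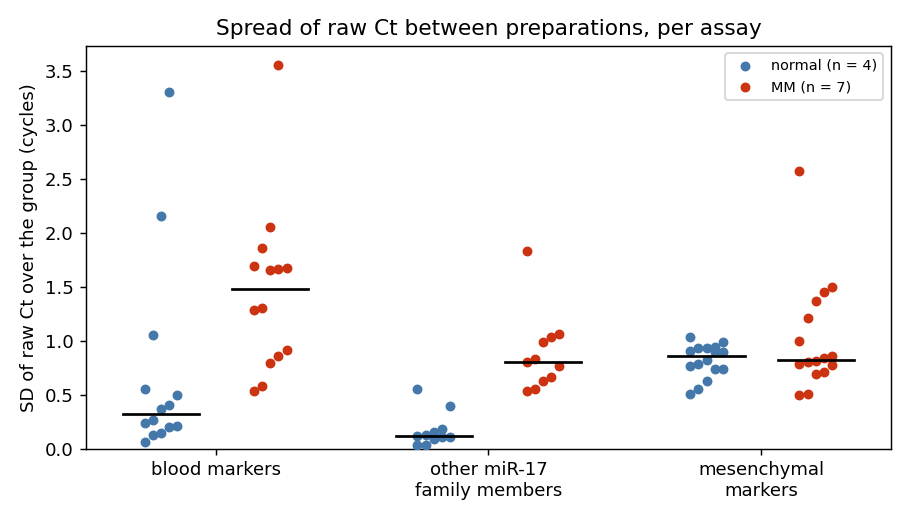
Standard deviation of raw Ct, in cycles, for single assays detected in all 13 preparations; each point is 1 assay, blue for the 4 normal and red for the 7 MM preparations, and black lines are medians. The blood markers and the miR-17 clusters sit low in the normal group (medians 0.32 and 0.12), while the mesenchymal markers sit at 0.86 there and 0.82 in MM; miR-363, a member of both other sets, is drawn with the blood markers.

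Fewer miRNAs were detected in MM than in normal preparations, and those detected in all samples needed more cycles. The number of assays with a Ct of 35 or below was 326.9 ± 15.7 in MM (SD, n = 7) and 357.5 ± 8.1 in normal (n = 4), a difference of 30.6 (exact two-sided permutation p = 0.0121). Of the 7 MM preparations, 6 lay below all normal ones. The 2 MGUS preparations had 283 and 315. The mean Ct of detected assays was 26.30 ± 0.37 in MM and 25.77 ± 0.06 in normal (exact two-sided permutation p = 0.0182), higher than every normal value in 7 of 7. The MGUS values were 26.75 and 25.97. Over the 242 assays detected in all 13 preparations, the mean Ct was 24.65 ± 0.68 in MM and 23.59 ± 0.26 in normal, a rise of 1.05 cycles (exact two-sided permutation p = 0.0212).

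**Figure D2:**
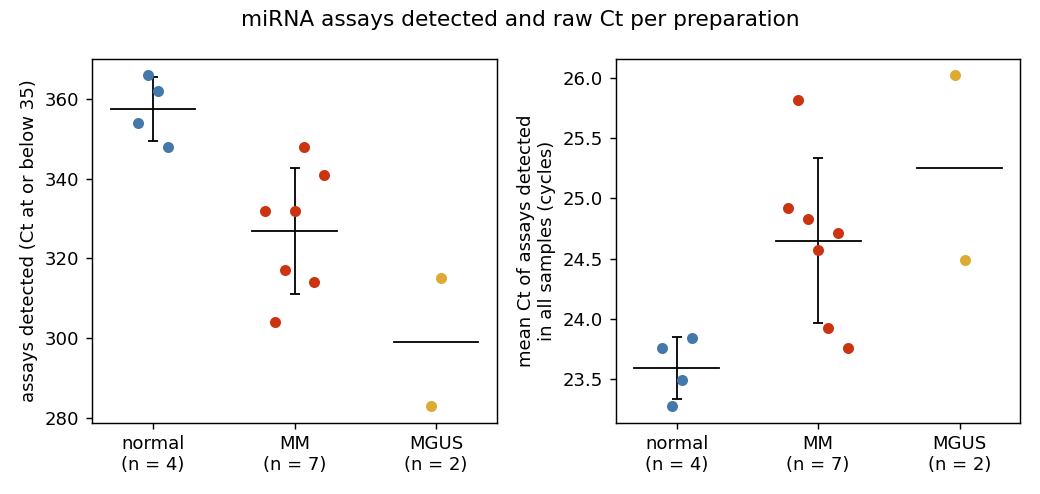
Left, number of assays with Ct at or below 35; right, mean raw Ct in cycles over the 242 assays detected in all samples. Points are preparations, lines are group means and bars are SD (normal and MM only); MM preparations range from 304 to 348 detected assays against 348 to 366 in normal.

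No single assay passed a test of unequal detection between MM and normal after adjustment, but the sample sizes allowed hardly any call. With 4 against 7 samples, Fisher's p cannot fall below 0.00303. After adjustment over 192 assays, an assay split perfectly by group could pass only together with others like it. Of 192 assays detected in some but not all of these 11 samples, none passed Fisher's exact test with adjustment, and 2 had an unadjusted p under 0.05. The share of detected samples was lower in MM for 143 of these assays and higher for 49. miR-1254 was detected in 4 of 4 normal and 1 of 7 MM preparations (Fisher's exact p = 0.0152, adjusted p = 1). miR-18b, a member of the miR-17 paralogs, was detected in 3 of 4 and 0 of 7 (Fisher's exact p = 0.0242, adjusted p = 1). miR-1183, miR-15b# and miR-545 were detected in 4 of 4 normal and 2 of 7 MM preparations. In the other direction, miR-211 and miR-767-3p were detected in 0 of 4 normal and 4 of 7 MM preparations, miR-603 in 0 of 4 and 3 of 7, and miR-1249 and miR-190b in 3 of 4 and 7 of 7.

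For MM against normal, the assays with the strongest evidence for a lower level were miR-589_001543, miR-573, miR-618, miR-592 and miR-1255B, all of which stayed short of the threshold. With limma, 0 of 364 assays passed an adjusted p of 0.05; 44 had an unadjusted p under 0.05, 5 upward and 39 downward, where 18.2 are expected by chance. An exact permutation test per assay called 0, with 48 at an unadjusted p under 0.05. Its p cannot fall below 0.00303, so an assay at that floor could pass adjustment over 364 assays only together with many others. Its 0 calls therefore add little to those of limma. Normalization to each sample's own detected assays left the median of all 364 log2 fold changes at −0.54, and normalization to the assays detected in all samples put it at −0.02; values below are given with that offset in them unless stated. Under the second normalization 31 assays had an unadjusted p under 0.05, 12 upward and 19 downward, and 0 were called.

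miR-589_001543 had a log2 fold change of −3.13 (SE 0.60, limma adjusted p = 0.0701), lower than all normal samples in 7 of 7 MM samples. It was called with a limma adjusted p of 0.00442 with array weights, 0.0132 without normalization, 0.00308 without MM 1 and 0.0463 without MM 4. miR-618 had −2.68 (SE 0.67), also lower in 7 of 7; miR-592 had −2.53 (SE 0.64), lower in 5 of 7; and miR-1255B had −3.11 (SE 0.80), lower in 6 of 7, each with a limma adjusted p of 0.146. Without normalization miR-618 (adjusted p = 0.0248) and miR-1255B (0.0469) were called, without MM 4 miR-618 and miR-592 (0.0463 each), and without MM 3, 4, 5 and 7 miR-592. miR-589_001543 was detected in 3 of 7 MM samples, miR-592 and miR-1255B in 4 of 7 each and miR-618 in 6 of 7, so these values depend on the limit of Ct 35; with normalization to the assays detected in all samples miR-589_001543 was −2.61, miR-618 −2.16, miR-592 −2.004 and miR-1255B −2.58. Over all alternatives run, miR-589_001543 ranged from −6.03 to −0.94, miR-618 from −3.21 to −1.11, miR-592 from −4.85 to −0.64 and miR-1255B from −5.05 to −1.03, in each case smallest in size with the limit at Ct 32. miR-573 was either strong or missing. It read Ct 18.87 to 21.96 in 3 normal samples and was not detected in normal 2, and it was detected in 1 of 7 MM samples. Its log2 fold change was −10.56 (SE 2.40, limma adjusted p = 0.146), with −14.34 without normal 2 (limma adjusted p = 5.3e-08), −8.92 without normal 1 and −7.92 with array weights; it was also called without normalization (adjusted p = 0.0383).

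The assays with the smallest p upward in MM were one printed as miR-139#_002145, miR-767-3p, miR-511, miR-211 and miR-378_002243. The first had a log2 fold change of 1.88 (SE 0.51, limma adjusted p = 0.146), above all normal samples in 6 of 7; the number in its name is uncertain. miR-511 had 3.46 (SE 1.34), above all normal samples in 5 of 7, and 2.02 without normal 3 and 4.60 without normal 1. It was detected in 3 of 4 normal samples, so its value depends on the limit of Ct 35. miR-767-3p had 3.93 (SE 1.35) and miR-211 had 4.44 (SE 1.83); neither was detected in a normal sample or in 3 of 7 MM samples, so both values depend on the limit of Ct 35. miR-378_002243 had 6.76 (SE 3.05, limma adjusted p = 0.400), with all of the difference in MM 3, 4, 5 and 7.

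Those 4 preparations, which carry the highest running numbers in the labels, lay apart from the other 9 by more than 1 cycle in 4 assays, all on card B. Their miR-378_002243 read Ct 12.49 ± 0.60 (SD, n = 4) against 25.22 ± 1.14 in the other 9. Their miR-222# read 26.62 against 32.86, their miR-425# 26.85 against 31.47, and miR-767-3p was detected in 4 of 4 and 0 of 9. Of all 715 ways to part 4 samples from 9, this one separated the most assays; the next separated 3 and the mean was 0.09. The 4 are all MM samples, so no comparison with normal can be made among them. The 4 normal preparations carry the lowest running numbers, so an effect of running number cannot be told apart from the group. With these 4 left out, 2 assays were called lower in MM, miR-1183 at −6.23 and miR-592 at −3.40 (limma adjusted p = 0.0128 and 0.0246), and the log2 fold change of miR-378_002243 was −0.63.

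miR-15a, which belongs to the miR-15/16 family of regulators of cell division and survival, was chosen before the data were examined because the study is known to have followed it up. It read Ct 28.72 ± 0.39 in normal (SD, n = 4) and 32.97 ± 1.86 in MM (n = 7), and it was detected in all 11. Its log2 fold change was −3.72 (SE 1.07), or −3.17 relative to the median of all assays, and it was lower than all normal samples in 6 of 7 MM samples. The exact two-sided permutation p was 0.0152, with an adjusted value of 0.315 over all assays, and the limma adjusted p was 0.185. The value of 0.315 was also the smallest that the permutation test gave for any assay after adjustment. MM 1 had a normalized level of −2.98, between the normal values of −3.40 and −2.52. The call was reached with limma's array weights, at −4.17 (adjusted p = 0.0383).

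The other 6 measured members of the miR-15/16 family had negative log2 fold changes, as had 78.6% of all 364 assays under this normalization. They were −2.45 (SE 1.24) for miR-503, −1.88 (SE 0.98) for miR-497, −1.01 (SE 0.49) for miR-15b, −1.01 (SE 0.72) for miR-424, −0.97 (SE 0.43) for miR-195 and −0.64 (SE 0.37) for miR-16. With normalization to the assays detected in all samples, these 6 were −1.92, −1.36, −0.49, −0.49, −0.44 and −0.12. Without normal 3, miR-424 was −0.34 and miR-503 was −1.61. As a list, the family ranked first in MM against normal but did not pass (camera adjusted p = 0.165, and adjusted p = 0.955 with an estimated correlation). With p adjusted over the list alone, 1 member passed, miR-15a (adjusted p = 0.0305); since the study is known for this miRNA, neither value is independent evidence. In the MGUS samples, miR-15a was not detected in MGUS 1 and read Ct 29.38 in MGUS 2.

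**Figure D3:**
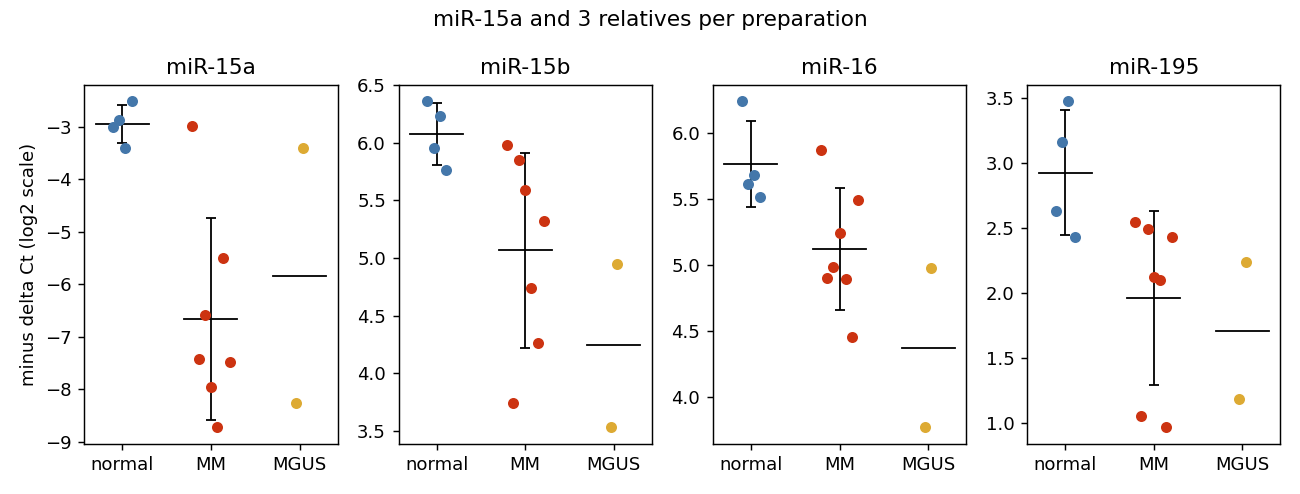
Normalized level (minus delta Ct, log2 scale, higher means more miRNA) of miR-15a, miR-15b, miR-16 and miR-195; points are preparations of the 4 normal, 7 MM and 2 MGUS donors, lines are means and bars are SD (normal and MM only). miR-15a lies between −3.40 and −2.52 in normal and between −8.72 and −2.98 in MM; MGUS 1 is at its detection limit.

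None of 22 miRNA lists passed in MM against normal with camera at a preset correlation; 2 had an unadjusted p under 0.05, and with an estimated correlation the smallest adjusted p was 0.955. fry, which asks whether a list moves one way on balance, gave no adjusted p under 0.116. All 16 mesenchymal markers had negative values, with a median of −0.76, or −0.22 relative to all assays (camera adjusted p = 0.471). Examples were miR-199b-5p at −1.91 (SE 0.77), miR-199a-5p at −1.29 (SE 0.55), miR-214 at −1.10 (SE 0.48) and miR-222 at −1.05 (SE 0.48). Nearer to the general offset were miR-199a-3p at −0.87 (SE 0.47), miR-145 at −0.79 (SE 0.46), miR-21 at −0.73 (SE 0.62) and miR-125b at −0.53 (SE 0.36), of which miR-125b turned to 0.08 when each card was normalized to its assays detected in all samples. Without normal 3, these 4 were −0.52, −0.34, −0.43 and −0.22. miR-221 had −0.31 (SE 0.44), turned positive under 3 other normalizations, and was −0.03 without normal 3 and −0.62 without normal 1.

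White blood cell markers had a median of −0.07, or 0.48 above the median of all assays (camera adjusted p = 0.471). miR-146a, which is induced by inflammatory signals, had 3.01 (SE 2.02) with a spread of several cycles in both groups, and 1.89 without normal 3 and 4.53 without normal 1. miR-223 had −0.07 (SE 0.40), miR-142-3p −0.64 (SE 0.78) and the red cell miRNA miR-451 −0.86 (SE 0.60). Of these, miR-223 turned positive under 4 other normalizations. Without MM 2 miR-142-3p was −0.28 and miR-451 −0.53, and without MM 1 they were −1.12 and −1.05. Red cell markers had a median of −0.61 and liver markers −0.61, with miR-122 at 0.24 (SE 0.51), −0.29 without normalization, 0.089 without normal 1 and 0.52 without normal 3. The medians were −1.07 for muscle, −0.06 for epithelial and −0.99 for neural markers, with miR-128 at −1.05 (SE 0.40) in the last. The camera adjusted p of these 5 lists ranged from 0.573 to 0.974.

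None of the other families and clusters passed, and their medians relative to all assays ranged from −0.62 for the miR-23, miR-27 and miR-24 clusters to 0.85 for the miR-221 and miR-222 cluster. The miR-17 clusters had a median of −0.50, with miR-25 at −0.68 (SE 0.36) and miR-93 at −0.53 (SE 0.30), the latter 0.08 with each card normalized to its assays detected in all samples. The list of miRNAs known as raised in myeloma plasma cells, which shares most of those members, had −0.46. The let-7 family, regulators of differentiation, had −0.18, with let-7a at −0.18 (SE 0.57) and let-7b at −0.18 (SE 0.42), and both turned positive under 3 other normalizations. The medians were −0.40 for the miR-29 family, −0.42 for the miR-30 family, −0.53 for the miR-99, miR-100 and miR-125 clusters, −1.17 for the miR-23, miR-27 and miR-24 clusters and −0.86 for the miR-130, miR-301 and miR-148 group. The p53-linked miRNAs had −0.64, with miR-34a at 0.08 (SE 0.45). The miR-221 and miR-222 cluster had 0.31, which rests on the passenger strands; miR-222# read Ct 26.62 in MM 3, 4, 5 and 7 and 34.18 in the other 3 MM samples. The imprinted cluster at 14q32 had −0.64 over 33 members, with miR-369-5p at −1.52 (SE 0.50). Their camera adjusted p ranged from 0.573 to 0.851.

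Of the lists linked to a process, osteoblast differentiation had a median of −0.10 (camera adjusted p = 0.573). Within it miR-218, which promotes osteoblast differentiation, had −1.28 (SE 0.37), lower than all normal samples in 6 of 7 (limma adjusted p = 0.185, and 0.0456 when adjusted over the list alone). Inflammation-linked miRNAs had −0.79, with miR-212 at −1.01 (SE 0.41), and hypoxia-linked miRNAs had −1.01, with miR-210 at −0.77 (SE 0.60), or −0.47 without MM 1. Their camera adjusted p were 0.851 and 0.837. In all 22 lists, adjustment over the list alone gave 1 passing member in the miR-15/16 family, 1 in osteoblast differentiation and 0 in the others. The direction of the camera test, which compares a list with all other assays, was opposite to the sign of the list's median relative to all assays for the miR-17, miR-30, miR-99 and myeloma lists, and for the inflammation, red cell, muscle and liver lists.

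**Figure D4:**
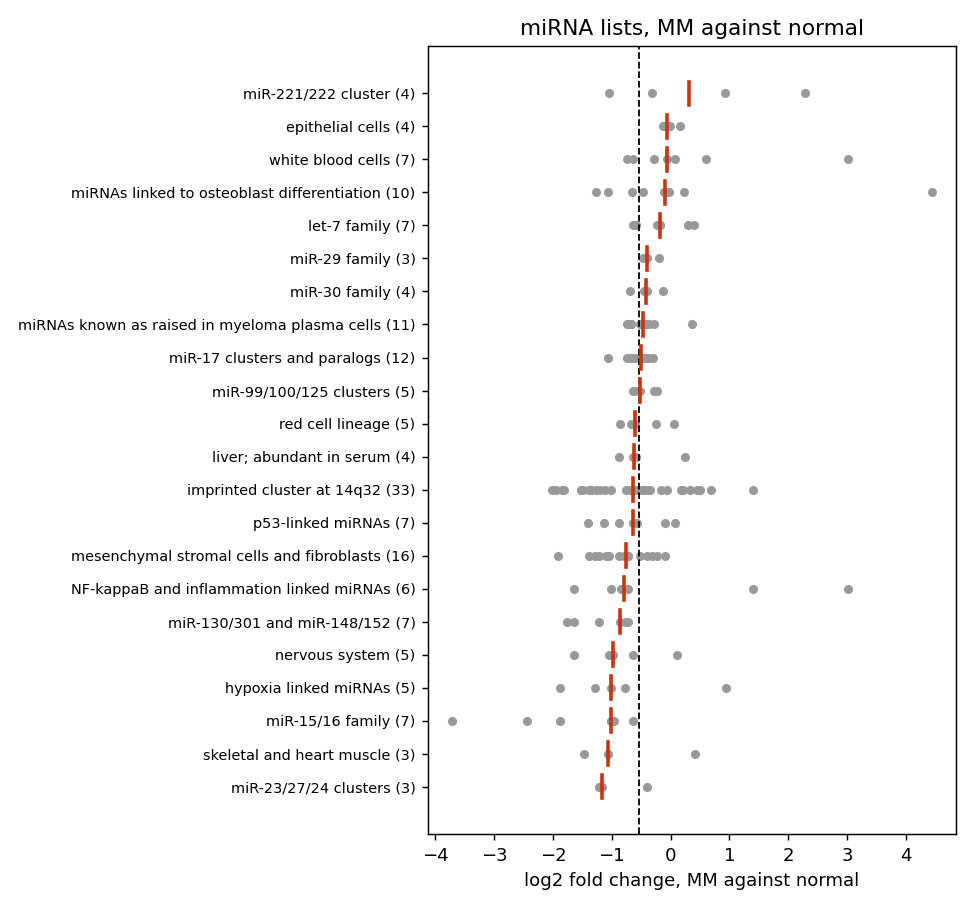
Log2 fold change, MM (n = 7) against normal (n = 4), of each tested member (grey points) of the 22 lists, with the list median in red and the median of all 364 assays (−0.54) as a dashed line; the number of tested members stands in parentheses. The miR-15/16 family extends furthest to the left, to −3.72 for miR-15a.

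For MGUS against normal, with 2 against 4 donors, 0 of 364 assays passed with limma, and 72 had an unadjusted p under 0.05, 1 upward and 71 downward. The median of all assays was −1.10, and −0.02 with normalization to the assays detected in all samples, under which 24 assays had an unadjusted p under 0.05, 8 upward and 16 downward. miR-589_001543, miR-592, miR-1255B and miR-744# were detected in 4 of 4 normal and 0 of 2 MGUS samples. Their log2 fold changes, which depend on the limit of Ct 35, were −3.83 (SE 0.83), −3.57 (SE 0.88), −4.03 (SE 1.11) and −5.34 (SE 1.44), or −2.73, −2.47, −2.93 and −4.24 relative to the median of all assays. miR-618 had −3.72 (SE 0.93). All 5 had a limma adjusted p of 0.166. Upward, the assay printed as miR-139#_002145 had 2.06 (SE 0.70), miR-603 had 1.05 (SE 0.56), miR-511 had 3.05 (SE 1.85), miR-766 had 4.42 (SE 2.71) and miR-520c-3p had 1.15 (SE 0.74). Of these 5, miR-511 was detected in 3 of 4 normal samples and miR-766 in 2 of 4, while miR-603 was detected in 0 of 4 normal and 1 of 2 MGUS samples. These 3 values thus depend on the limit of Ct 35. miR-767-3p, detected in 0 of 4 normal and 0 of 2 MGUS samples, had 0.58 in the same comparison. That value comes from the limit and the normalization alone, so part of the 1.05 of miR-603 can come from them too. The limma adjusted p of the 5 upward assays ranged from 0.166 to 0.341. Single samples moved some of them: without normal 3, miR-511 was 1.61; without MGUS 1, the assay printed as miR-139#_002145 was 1.37 and miR-520c-3p 2.42; without MGUS 2, miR-603 was 1.90 and miR-520c-3p −0.13. With only the 2 groups in the fit, 8 assays were called lower in MGUS; without MGUS 2, 7 were, with MGUS 1 assumed to vary like the other groups.

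No list passed in MGUS against normal with camera (1 at an unadjusted p under 0.05, smallest adjusted p 0.241 for the miR-17 clusters, and adjusted p = 0.959 with an estimated correlation). All 12 tested members of the miR-17 clusters had negative values, with a median of −1.18, which is −0.08 relative to all assays. The let-7 family had a median 0.72 above that of all assays and the mesenchymal markers 0.10 above it. When adjusted over each list alone, 1 member passed, miR-128 of the neural list (adjusted p = 0.0349).

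For MM against MGUS, miR-573 was the assay with the smallest p. It was detected in 2 of 2 MGUS and 1 of 7 MM samples, with a log2 fold change of −15.60 (SE 3.07, limma adjusted p = 0.0894). Of 364 assays, 0 passed with limma and 14 had an unadjusted p under 0.05, 11 upward and 3 downward. The median of all assays was 0.60; with normalization to the assays detected in all samples it was 0.05, and 7 assays had an unadjusted p under 0.05, 4 upward and 3 downward. miR-573 was called with quantile normalization (adjusted p = 0.0456), with the 2 groups alone, and without normal 2. The other 4 with the smallest p downward were miR-1305 at −3.49 (SE 1.87), miR-545 at −2.27 (SE 0.88), miR-645 at −2.15 (SE 1.18) and miR-520c-3p at −1.54 (SE 0.68). Those with the smallest p upward were miR-381 at 3.97 (SE 1.48), miR-628-5p at 3.15 (SE 0.95), miR-206, known from skeletal muscle, at 2.86 (SE 1.05), miR-95 at 2.80 (SE 0.90) and miR-454 at 1.24 (SE 0.46), each with an adjusted p of 0.742. Several of these values rested on 1 of the 2 MGUS samples. Without MGUS 1, miR-206 was −0.03, miR-381 −0.04, miR-628-5p 1.02, miR-95 3.97, miR-545 −1.21 and miR-520c-3p −2.82. Without MGUS 2, they were 5.74, 7.98, 5.28, 1.63, −3.33 and −0.26, and the first 3 were among 5 assays called. Of 22 lists, 0 passed with camera and 3 had an unadjusted p under 0.05, the miR-17 clusters upward and the mesenchymal markers and the miR-99, miR-100 and miR-125 clusters downward relative to all assays, each with an adjusted p of 0.338 (smallest adjusted p = 0.842 with an estimated correlation).

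The changes in MM and in MGUS against normal had a Pearson correlation of 0.54 across the 364 assays, which are not independent replicates, and a covariance of 1.15. Both comparisons share the 4 normal samples. In 100 simulated sets of unchanged groups against shared controls, the median correlation was 0.51 and 43 were as high. The median covariance was 0.56 and 17 were as high. Each simulated sample took its deviations from any of the 13 samples, drawn with replacement, so simulated controls could carry the spread of patients. Over the assays detected in all samples, the median SD of raw Ct was 0.60 in normal and 1.00 in MM. The simulated values may thus be too high and cannot decide whether 0.54 exceeds that of unchanged groups. With the normal samples split so that each comparison had its own 2, the correlation averaged 0.28 over 6 splits, from 0.10 to 0.44.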

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

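The tests on miR-15a, on the release of miRNAs, on assays chosen by the normal samples and the alternatives that leave out MM 3, 4, 5 and 7 were chosen after the results were seen; those on abundant against rare assays, on the cards and on other splits were chosen before.

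Of 114 groups of 4 or 7 samples examined, 4 held a sample far from the others; chance flags about 1 in 20 groups, or 5.7 here. The normalized level of miR-206 was −1.38 in normal 3 and 0.11 to 0.38 in the other normal samples. That of miR-146a was 0.49 in MM 3 and 7.49 to 11.47 in the other MM samples. miR-1254 in MM 5 (−5.71) and miR-545 in MM 6 (−5.88) stood above the others (−9.12 to −8.03), most of which were not detected.

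Fewer assays were detected in MM, and the raw Ct of assays detected in all samples was higher by a median of 1.04 cycles in MM (234 of 242 assays) and 1.64 in MGUS. A fault of 1 card is argued against as the cause of the median rise, since the smaller median rise of the 2 cards was 0.857 of the larger. This ratio of group medians cannot see a fault in single preparations. There the shift of the authors' constants differed between the cards by 0.006 in MM 4 up to 1.76 in MM 2. Less amplifiable small RNA in the whole preparation stays open. The 61 rarest of these assays rose by only 0.105 cycles more than the 61 most abundant. That set leaves out assays lost in patients. Among 305 assays chosen by the normal samples alone, with lost assays kept, the difference was 0.41 (bootstrap SE 0.23). Choosing and ranking assays by the normal readings can itself raise this difference. The bootstrap also runs over assays and not over donors. Each reverse transcription took 60 ng of RNA, so the Ct does not measure the amount released. A lower share of miRNAs in the RNA released by the patients' cells would give the same rise of 1.04 cycles. This and less amplifiable small RNA cannot be told apart, because no measure of RNA quality, miRNA share or vesicle number is at hand. The disease itself stays open as an untested cause. The normal preparations carry the lowest running numbers in the labels, so an effect of running number cannot be told apart from the group either.

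miR-15a was lower in 6 of 7 MM samples. Less amplifiable small RNA that shifts all assays alike is argued against as the whole cause. Normalization to the assays detected in all samples left the log2 fold change at −3.19 (SE 1.08). The raw Ct of miR-15a rose by 4.25 cycles. The 43 assays of like Ct in normal rose by a median of 1.67, and 2 of them by as much as miR-15a. In MM 2, 4, 5 and 7 miR-15a read Ct 33.37 to 34.68, near the limit of Ct 35. A shift of the mean does not test whether rare miRNAs were lost more than others there. A run shared by MM 3, 4, 5 and 7 cannot be told apart from the disease with 3 MM samples left, at −2.35 (SE 1.27). The other strand of the hairpin, miR-15a#, had −0.91 (SE 0.67), with a difference of the strands of −2.81 cycles (exact two-sided permutation p = 0.0515). From the neighbouring hairpin on chromosome 13, miR-16-1# had −2.74 (SE 0.83, limma adjusted p = 0.192). It was detected in 5 of 7 MM samples, so this value depends on the limit of Ct 35. miR-16, which comes from that hairpin and from another on chromosome 3, had −0.64 (SE 0.37). Less of the miR-15a precursor stays open. A lower level of miR-15a in MM stays a hypothesis, since it did not pass adjustment over 364 assays (limma adjusted p = 0.185).

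The 44 assays at an unadjusted p under 0.05 were set against 100 splits of the 11 samples into 4 and 7, the real one included. Of these splits, 6 gave as many, again with the real one counted, and the highest other gave 58. Chance cannot be excluded. For the 0 assays and 0 lists called, every split gives as many by construction (100 of 100 splits for each), which decides nothing; the highest other split called 6 assays and 7 lists.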

How the results depend on the processing

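Raw Ct, the common mean within each card and leaving out MM 3, 4, 5 and 7 or MM 2 and MGUS 1 were chosen after the results were seen. The difference in detected assays (−40.8 to −26.8) and in mean raw Ct (0.42 to 0.76) kept its direction and stayed past the threshold under all alternatives run. Fisher's test called 0 in all, which decides little, since its smallest possible p is too large for a lone assay to pass.

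Assays called in MM against normal numbered 1 with the authors' table, 2 with array weights, 5 without normalization, 2 without MM 3, 4, 5 and 7, and 0 to 4 leaving out each sample (1 without normal 2, 1 without MM 1 and 4 without MM 4). In MGUS against normal they numbered 1 at Ct 40, 2 with the authors' table, 8 with only the groups compared, 2 with the replicate block, 2 without normalization, 2 without MM 3, 4, 5 and 7, and 0 to 7 leaving out each sample (1 without MM 1 and 7 without MGUS 2). In MM against MGUS they numbered 1 at Ct 40, 1 with quantile normalization, 1 with only the groups compared, and 0 to 5 leaving out each sample (1 without normal 2 and 5 without MGUS 2). Lists called numbered 1 in MGUS against normal at Ct 40 and, in MM against MGUS, 2 with the authors' table and 0 to 1 leaving out each sample (1 without MM 1). A group left with 1 sample was assumed to vary like the others.

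miR-15a stayed lower under all alternatives run, from −4.33 to −2.35 (limma adjusted p 0.0383 to 0.697), and passed only with array weights (−4.17). With the replicate block it was −3.29 (limma adjusted p = 0.320) and 0 assays were called in MM against normal. The numbers do not pair samples: changes of MM and normal samples with the same number correlated at 0.40, −0.02, 0.09 and 0.06. The correlation of MM and MGUS changes ranged from 0.40 to 0.61 leaving out each sample.

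Reversed were, with the common mean, miR-223 (0.46), miR-221 (0.21), let-7a (0.34) and let-7b (0.35); within each card, miR-223 (0.54), miR-125b (0.081), miR-221 (0.30), let-7a (0.43), let-7b (0.43) and miR-93 (0.081); with quantile normalization, miR-223 (0.26), miR-221 (0.37), let-7a (0.24) and let-7b (0.24). miR-223 was 0.019 with the mean within each card, 0.00064 with array weights, 0.17 with the replicate block and 0.064 without MM 2 and MGUS 1. miR-34a was −0.061 with the authors' table, −0.49 with the replicate block, −0.45 without normalization and −0.058 without MM 3, 4, 5 and 7, which put miR-378_002243 at −0.63. miR-122 was −0.29 without normalization, and miR-206 in MM against MGUS −0.10 without MM 2 and MGUS 1. Leaving out each sample gave −0.23 to 0.078 for miR-223, −0.087 to 0.27 for miR-34a, −0.69 to 0.39 for let-7a, −0.40 to 0.11 for let-7b, −0.13 to 2.42 for miR-520c-3p (MGUS against normal), −0.026 to 5.74 for miR-206 and −0.041 to 7.98 for miR-381 (MM against MGUS). Apart from the offset between normalizations and the samples left out, the cause was not tested. Normalization to small-RNA controls was not run. Readings near Ct 35 limit what can be compared.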

Other observations

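Both tests in this part were chosen after the result was seen.

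Blood cell miRNAs were abundant in preparations from cultured stromal cells, with miR-223 at Ct 15.63, miR-150 at 16.17 and miR-451 at 17.19 in normal. The medium held bovine serum, pre-cleared by ultracentrifugation per the labels. In the 4 normal cultures, the median SD of raw Ct of the blood markers was 0.371 of that of the mesenchymal markers; this low spread prompted the idea of one outside source in like amount and is no separate test of it, and the miR-17 clusters, of which 1 member (miR-363) is among the blood markers, had a lower spread still (0.12 cycles), so such a source stays open there. In the 7 MM cultures this ratio was 1.79. Raw Ct is read per 60 ng of RNA and not per culture. Neither ratio can therefore decide whether such a source was present in like amount. Blood cells left in the cultures, and release by the stromal cells themselves, were not tested. An effect of running number, lowest in the normal preparations, cannot be told apart from the group.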
